A study of Homo sapiens with 4 samples.

How the data were processed

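Enhanced crosslinking and immunoprecipitation (eCLIP) recovers the RNA fragments that ultraviolet light has joined to a chosen protein, here a FLAG-tagged copy of ZFR, a zinc finger RNA-binding protein of the DZF family. The size-matched input is made from RNA of the same gel region without the immunoprecipitation and measures the background of abundant RNA. The cells were Flp-In T-REx-293, a line derived from human embryonic kidney cells that carries a single site for integrating a transgene under a doxycycline-controlled promoter. Per the labels' protocols, the transgene was induced with 1 µg/mL doxycycline for 48 to 72 h and crosslinking used 400 mJ/cm2. The 4 libraries were grouped by their titles into 2 eCLIP libraries and 2 inputs, each numbered 1 and 2. No label says that the 2 libraries of a group came from separate cultures, so every p-value across libraries measures only the spread between these libraries, which may be technical.

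Per the submitters' processing notes, the reads were processed with cutadapt, STAR and SAMtools against the hg19 build; their versions, the peak caller, its settings and the gene annotation are not given in the sources used here. The authors deposited 1 list of peaks per library, so peaks were called in each library separately. Each line gives an interval and strand, a versioned gene identifier, the number of the peak within the gene and a whole number of at least 3, a p-value, and a position inside the peak. The deposited p-value of each peak lies between 0 and 0.05. The authors' score in each line is the whole part of 10 times the negative log10 of that p-value, capped at 1000, and this held for every peak with a p-value above 0. Where the p-value is 0, the score is 0. The whole number at the end of a peak's name was read as the reads in the peak, which the files do not state. The peak numbers within genes have gaps, so the lists hold part of the peaks that were numbered. A peak that lies in overlapping genes is listed once for each: such repeats made up 4.25% of the lines of eCLIP replicate 1, 6.53% of eCLIP replicate 2, 4.50% of input 1 and 6.44% of input 2. Because whole libraries were not counted here, the sequencing depth is unknown, and sums of reads in peaks move with how much was called.

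The files pair no gene name with the 17764 gene identifiers, and none of them matched the reference table of 59792 genes, in which 0 genes carry an Ensembl identifier and which follows another genome build. The 16 gene lists fixed in advance were therefore not tested. The classes of exon and intron, the distances to splice sites and the sequence of the peaks were not analysed here, because no hg19 annotation or sequence was used. Regions are given by hg19 coordinates, counted from 1, with at most 2 identifiers in each direction.

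Peaks were called overlapping when they shared at least 1 base on the same strand. A reproducible eCLIP-only peak was a peak of eCLIP replicate 1 overlapped by a peak of eCLIP replicate 2 and by none of either input. Chance overlap was measured with 100 random placements of each peak within the span of its gene, from the first to the last base of that gene's peaks over the 4 libraries. The one-sided p counts placements with at least the observed overlap, and the smallest it can be is 0.0099. Lists of equal length held the 11204 peaks of each library with the lowest p-values, ties going to more reads. The p-values of shared and unshared peaks were compared with a two-sided permutation test of the difference in medians (100000 resamples), which compares peaks within a library and not conditions. Shares of a library carry Wilson 95% intervals, which cover counting error only.

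Genes were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend), two-sided, on log2(peaks per 10000 peaks of the library + 0.5), over all 4 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. The 8914 genes with at least 10 peaks over the 4 libraries were tested. Differences on this scale understate the change of genes with few peaks. Numbers of peaks are not read counts, so no count model was used. In simulated lists for these libraries, with counting noise alone, the fit recovered 13.5% of 200 genes changed 4-fold and 47.5% of 200 changed 16-fold. With the measured spread between libraries added, it recovered 2.5% and 35%, and it called 0 unchanged genes each time. That spread was the median residual SD of the fit (0.598), which already holds counting noise. Counting noise thus entered again, and the 2.5% and 35% may understate the recovery. An exact permutation test of 2 libraries against 2 cannot give a two-sided p below 0.33, so values per library are given in its place. Same-numbered eCLIP and input libraries were also compared gene by gene with Fisher's exact test.

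Before the data were examined, the text was set to name the 15 genes with the lowest adjusted p among those higher in eCLIP and the 5 among those lower, the 10 genes with most reproducible eCLIP-only peaks, up to 4 members of each gene list and certain fixed genes, and the 5 reproducible eCLIP-only peaks with the best sum of ranks of the p-values in both eCLIP libraries. Only the 10 regions and the 5 peaks could be given, since no gene passed the threshold and the others needed names. 1 gene among the 10 was left out under an exclusion written into the same rule, and the next took its place. That gene was recognised by its identifier from general knowledge, since no table used here gave names, so the 10 are not the full list of the highest counts. The alternatives tried were a p-value limit of 0.001, an overlap of 50% of the shorter peak, strand ignored, peaks within 50 bases merged, lists of equal length, other handling of the inputs, pseudocounts of 0.1 and 2, other limits on peak number, voom, covered bases, the replicate number as a block, and each library left out. The position of peaks along genes, with spans as above, was added after the data were seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 did the remaining work, and matplotlib 3.10.9 drew the figures.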

Results

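Binding of FLAG-tagged ZFR to RNA was mapped by eCLIP in Flp-In T-REx-293 cells, with 2 eCLIP libraries and 2 size-matched inputs. The lists held 479308 peaks in 15839 genes for eCLIP replicate 1 and 41904 peaks in 7728 genes for eCLIP replicate 2. Input 1 held 63068 peaks in 11275 genes and input 2 held 11204 peaks in 5891 genes. The reads in peaks came to 3075352 and 229647 in the eCLIP libraries and to 249245 and 102084 in the inputs, a mean of 6.42 and 5.48 reads per peak against 3.95 and 9.11. The median peak was 28 bases wide in all 4 libraries, and the peaks covered 13508370, 1190443, 1511132 and 313854 bases in the same order. Many peaks rested on the minimum of 3 reads: 32.0% in eCLIP replicate 1, 50.1% in eCLIP replicate 2, 62.3% in input 1 and 49.2% in input 2.

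**Figure D1:**
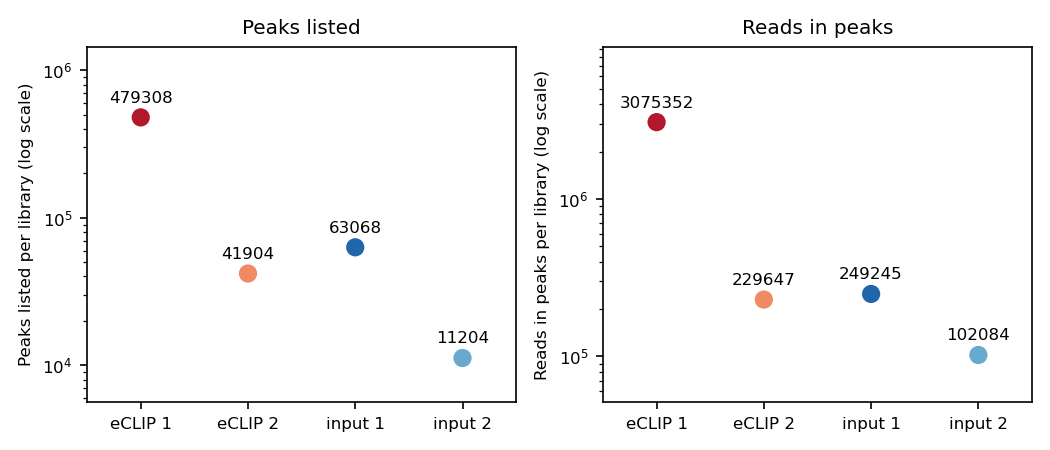
Peaks listed (left) and reads in peaks (right) per library, each point 1 library, on log axes. eCLIP replicate 1 stands apart at 479308 peaks, while eCLIP replicate 2 (41904) lies between input 1 (63068) and input 2 (11204).

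The first comparison asked how far the peaks of the 2 eCLIP libraries lay at the same positions. In eCLIP replicate 2, 13877 peaks, or 33.1% (95% interval 32.7 to 33.6), overlapped a peak of eCLIP replicate 1. Placed at random within the same genes, 9.74% of them did, so the observed overlap was 3.40 times that of the placements (one-sided permutation test by placement, p = 0.0099, the smallest that 100 placements can give). Every other pair of libraries, also those with an input, reached the same p, so it does not set the eCLIP pair apart. Only 3.55% (3.38 to 3.73) of the eCLIP replicate 2 peaks overlapped a peak of input 1, although that list was the longer of the inputs, and 5.21% (5.00 to 5.42) overlapped one of input 2. Relative to placements the overlap with input 2 was the highest, at 5.02 times, against 2.18 times for input 1. With peaks placed within 10 kb of their position, a choice made after the data were seen, the ratios were 9.30 for input 2, 3.63 for input 1 and 3.53 for eCLIP replicate 1, so the overlap of the eCLIP libraries was the lowest of these. The overlap rose with the reads in a peak. Of eCLIP replicate 2 peaks with 3 reads, 28.0% (27.4 to 28.6) were found in eCLIP replicate 1, and of those with over 10 reads, 54.0% (52.0 to 56.0). Input 2 peaks met the same list as often at that size, since 54.4% (51.3 to 57.4) of those with over 10 reads overlapped a peak of eCLIP replicate 1.

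The peaks of input 2 overlapped those of input 1 more often the more reads they held. Input 2 peaks overlapped input 1 peaks in 18.4% (17.7 to 19.1) of cases, 3.60 times the placements within genes and 15.0 times those within 10 kb. That share was 5.28% (4.72 to 5.90) for peaks with 3 reads and 76.1% (73.4 to 78.6) for peaks with over 10 reads.

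With each list cut to its best-ranked 11204 peaks, the 2 eCLIP libraries shared more peaks than any other pair. Of the eCLIP replicate 1 peaks, 20.1% (19.4 to 20.8) overlapped one of eCLIP replicate 2, and 17.3% (16.6 to 18.0) did in the other direction. Pairs of an eCLIP library and an input lay between 4.67% (4.29 to 5.07), for eCLIP replicate 2 in input 1, and 12.9% (12.3 to 13.6), for eCLIP replicate 2 in input 2. The 2 inputs overlapped by 11.4% and 11.5%. The intervals of the eCLIP pair did not meet those of any other pair, though they cover counting error and not the spread between libraries. The cut kept the whole list of input 2, with 49.2% of its peaks at 3 reads, but only the best-ranked part of the others. Pairs with input 2 were thus not compared at equal peak strength. In the full lists, among peaks with over 10 reads, 76.1% of input 2 peaks met input 1 and 54.0% of eCLIP replicate 2 peaks met eCLIP replicate 1.

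**Figure D2:**
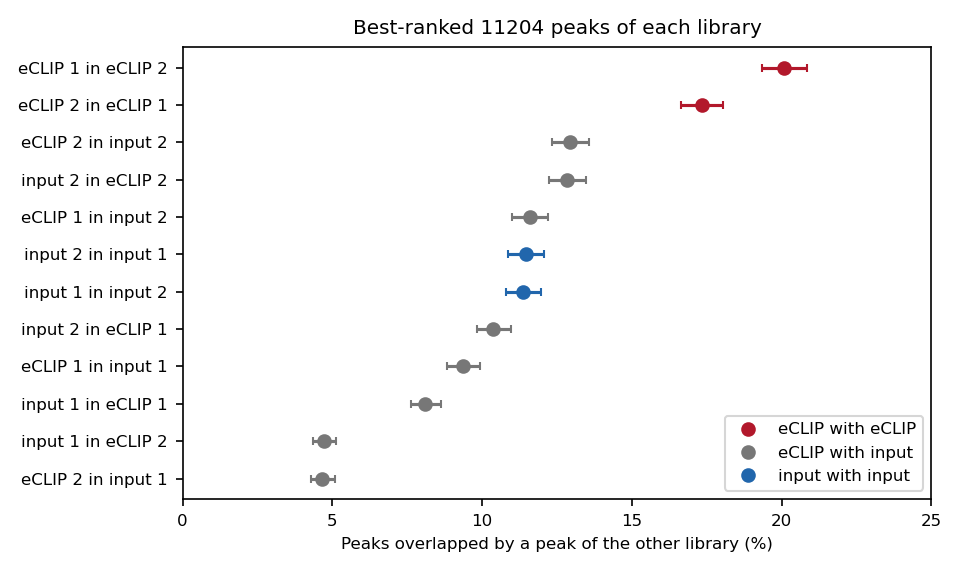
Share of the best-ranked 11204 peaks of each library (x axis, %) overlapped by those of another library, with 95% Wilson intervals; each row names a pair. The 2 eCLIP comparisons, at 20.1% and 17.3%, lie above every pair that includes an input. The list of input 2 is whole and the others are cut, so peak strength is not equal.

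The second comparison asked which peaks were found in both eCLIP libraries and in neither input. Of the 14167 peaks of eCLIP replicate 1 that were found again in eCLIP replicate 2, 12067 (85.2%) overlapped no input peak and 2100 did. Over the whole list of eCLIP replicate 1, 1.53% of peaks overlapped a peak of input 1 and 0.643% one of input 2. The shared peaks thus met input peaks more often than the list as a whole, and the 85.2% does not set them apart from it. The background counted by the same rule, input 1 peaks found in input 2 and in neither eCLIP library, was 1157 peaks. These 2 counts are not on an equal footing. The background came from shorter lists and had to miss the 479308 peaks of eCLIP replicate 1. In lists of equal length the eCLIP count was 1357, or 1237 counted on eCLIP replicate 2, and the background 754. Those lists held all peaks of input 2, so they were equal in length and not in peak strength. At a p-value limit of 0.001 the eCLIP count was 2486. The other pairs of libraries, counted the same way, gave 5500 peaks for eCLIP replicate 1 with input 1, 1287 for eCLIP replicate 1 with input 2, 264 for eCLIP replicate 2 with input 1, and 924 for eCLIP replicate 2 with input 2. The reproducible eCLIP-only peaks lay in 3903 genes, of which 1931 held 1 such peak and 238 held 10 or more. Those 238 genes took 33.3% of the peaks. The peaks had a median width of 33 bases and a median of 9 reads in eCLIP replicate 1, 49.2% lay on the minus strand, 11.4% on chromosome 19, and 36 on the mitochondrial chromosome.

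1 of the 10 genes with most reproducible eCLIP-only peaks was left out by a rule fixed beforehand, and the gene next in order was added. The 10 genes named here held between 37 and 87 such peaks each. The positions given for them run from the first to the last of these peaks. The counts and shares per library cover every peak listed for the gene, also outside those positions. The highest count, 87 peaks, lay on the minus strand of chromosome 1 between positions 21264953 and 21501185. In that gene the libraries listed 675 and 186 peaks for eCLIP and 107 and 37 for the inputs, or 14.1 and 44.4 against 17.0 and 33.0 per 10000 peaks. On the minus strand 39.6% of the distinct intervals of input 1 touched the next one, which raises its counts for genes on that strand. It also raises the total of input 1, which lowers its shares for genes on the plus strand. With touching and overlapping peaks merged, its 63068 peaks formed 44101 regions. The shares of the named regions were not repeated with touching peaks merged. A region on the plus strand of chromosome 17, from 29037366 to 29116051, held 50 peaks, and one on the plus strand of chromosome 4, from 20266401 to 20621592, held 45. The minus strand of chromosome 2 from 61727694 to 61764994, the plus strand of chromosome X from 73164557 to 73231174 and the minus strand of chromosome X from 73421133 to 73500072 held 44 each. The minus strand of chromosome 9 from 38545078 to 38620424 held 40, and the plus strand of that chromosome from 134269586 to 134339060 held 37. The minus strand of chromosome 14 from 21686815 to 21735617 held 39, as did the minus strand of chromosome 7 from 104889346 to 105023481. By share of the library's peaks, the gene on chromosome 7 was the 1 of the 10 in which both eCLIP libraries (9.49 and 24.1 per 10000) lay above both inputs (7.61 and 8.03 per 10000). Within same-numbered libraries, the eCLIP share was above the input share in both comparisons for 5 of the 10. The comparison with input 1 carries the limit given above: its shares are raised on the minus strand and lowered on the plus strand. Of the 5, the plus-strand region of chromosome 9 was close there, at 4.86 per 10000 in eCLIP replicate 1 and 4.44 in input 1.

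**Figure D3:**
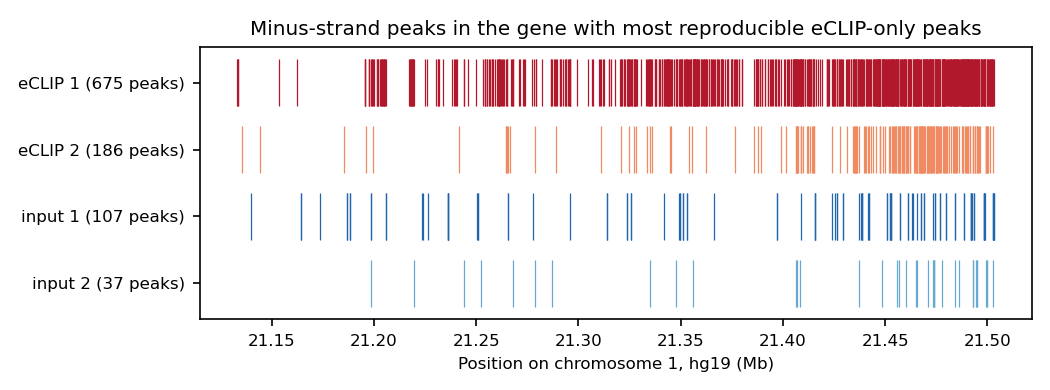
Peaks on the minus strand in the gene with most reproducible eCLIP-only peaks, along chromosome 1 (hg19, Mb), 1 row per library and 1 line per peak. The gene holds 675 and 186 peaks in the eCLIP libraries and 107 and 37 in the inputs.

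Of the 5 reproducible eCLIP-only peaks with the best p-values in both libraries, 4 lay on the plus strand of the mitochondrial chromosome. They spanned positions 2847 to 2851, 2864 to 2865, 2523 to 2526 and 2821 to 2826, with 828, 669, 725 and 869 reads in eCLIP replicate 1 and 275, 239, 264 and 345 in eCLIP replicate 2. These intervals were 2 to 6 bases wide, and an input 2 peak of 651 reads ended 1 base before the one at 2523. The remaining one lay on the plus strand of chromosome 19 at 49607795 to 49607840, with 321 reads in eCLIP replicate 1 and 98 in eCLIP replicate 2. An input 2 peak of 4 reads ended 2 bases before it and lay inside the overlapping eCLIP replicate 2 peak, which ran from 49607691 to 49607831, so this site was not free of input peaks when counted on eCLIP replicate 2. The deposited p-value was 0 for all 5 in eCLIP replicate 1, where 83 peaks had that value, and lay between 3.12e-148 and 4.42e-57 in eCLIP replicate 2. As shares of all reads in peaks, mitochondrial reads made up 3.47% and 8.57% in the eCLIP libraries and 1.67% and 30.5% in the inputs, which did not separate the groups.

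Peaks found in both eCLIP libraries were the stronger ones in each list. In eCLIP replicate 1 the authors' p-values had a median of 4.73 on the -log10 scale for the 14167 shared peaks and 1.95 for the 465141 others, a difference of 2.77 (two-sided permutation test, p = 1e-05, the smallest that the resamples can give). In eCLIP replicate 2 the medians were 2.07 for 13877 shared peaks and 1.69 for 28027 others, a difference of 0.383 with the same p. The shared peaks had a median of 10 reads against 4 in eCLIP replicate 1, and 4 against 3 in eCLIP replicate 2.

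The third comparison asked which genes took a larger or smaller share of the peaks in eCLIP than in the input. No gene passed the threshold in either direction: limma called 0 of 8914 genes higher and 0 lower, and the lowest adjusted p was 0.995. At an unadjusted p under 0.05, 112 genes were higher and 62 lower, fewer than the share of 0.05 of the 8914 genes that evenly spread p-values give. With peaks limited to a p-value of 0.001 these counts were 691 and 43 of 3334 genes, and with voom 83 and 523. The lean thus depended on the setting. After adjustment the 0.001 limit gave 0 genes in either direction, and voom called 0 higher and 8 lower. Fits with 1 library left out set a lone library against 2 and assume that it varies like the other group. Some of these fits called genes and others did not, and their counts are not read as differences between eCLIP and input. Both eCLIP shares lay above both input shares in 1881 genes (21.1%) and below both in 905 (10.2%), where a random order of the 4 libraries gives 16.7% each way. Both libraries numbered 2 lay below both numbered 1 in 3245 genes (36.4%) and above both in 1110 (12.5%). The 16.7% is not a clean baseline for these shares. The filter on summed peaks drew mostly on eCLIP replicate 1, with 479308 peaks, and input 2 had a peak in only 5891 genes. Many tested genes therefore had a share of 0 in the shorter lists, and list length and the filter shape these counts. Across genes, which are not independent replicates, log2 shares correlated at r = 0.722 between eCLIP replicate 1 and input 1 and at r = 0.651 between the 2 eCLIP libraries. The corresponding r was 0.536 for eCLIP replicate 2 with input 2 and 0.401 for the 2 inputs. In simulated lists limma recovered 13.5% of 200 genes changed 4-fold with counting noise alone. With the measured spread between libraries added it recovered 2.5%, which may be too low, since that spread already holds counting noise.

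Same-numbered libraries compared with Fisher's exact test, which sets 2 libraries against each other and not conditions, gave 167 genes higher and 417 lower in eCLIP for number 1, and 4 higher and 6 lower for number 2. The lists of number 1 held 479308 and 63068 peaks, and shares can move with list length. In eCLIP replicate 1, genes with spans over 100 kb held 50.1% of all peaks and 20.7% of the best-ranked 11204. The excess of lower genes is therefore not read as depletion in eCLIP. The test treats each listed interval as independent, yet 39.6% of the minus-strand intervals of input 1 touched the next one. This raises the input 1 counts of minus-strand genes. It also raises the total of input 1, which lowers its shares for plus-strand genes. The test was not repeated with touching peaks merged. In both comparisons 2 genes were higher and 3 lower, and 0 went opposite ways. Of these, 1 lower gene was left out by a rule fixed beforehand, and the other 4 were chosen after their values were seen. ENSG00000173065.9, on the minus strand of chromosome 17 with peaks from 27083647 to 27169577, held 187 and 63 peaks in the eCLIP libraries and 5 and 1 in the inputs, or 3.90 and 15.0 against 0.793 and 0.893 per 10000 peaks. ENSG00000175175.4, on the plus strand of chromosome 17 from 56833923 to 57034974, held 326 and 45 peaks in eCLIP against 23 and 0, or 6.80 and 10.7 against 3.65 and 0 per 10000, and input 2 listed no peak in it. For number 1 its adjusted p in Fisher's exact test was 0.042, near the threshold. ENSG00000167978.12, on the plus strand of chromosome 16 from 2802699 to 2821386, held 44 and 12 peaks in eCLIP against 23 and 19, or 0.918 and 2.86 against 3.65 and 17.0 per 10000. ENSG00000251562.3, on the plus strand of chromosome 11 from 65266524 to 65273451, held 74 and 26 against 28 and 25, or 1.54 and 6.20 against 4.44 and 22.3 per 10000. By share of the reads in peaks, a measure added after the data were seen, the lower direction of these last 2 genes held for number 2. For number 1 it was reversed for ENSG00000251562.3 and the shares were nearly even for ENSG00000167978.12. ENSG00000251562.3 took 31.9 per 10000 reads in eCLIP replicate 1 against 16.8 in input 1, and 24.7 in eCLIP replicate 2 against 30.3 in input 2. For ENSG00000167978.12 the shares were 4.47 against 4.33 and 2.74 against 10.1. Touching intervals of input 1 may repeat the same reads: 57.7% of its reads lay on the minus strand, against 47.1% of its covered bases. A raised read total lowers the input 1 shares of these 2 plus-strand genes, so the 4.47 against 4.33 sets no direction. The other 2 genes were higher in eCLIP by reads in both comparisons, at 4.37 against 0.682 and 12.2 against 0.294 for ENSG00000173065.9, and at 5.91 against 3.17 and 8.88 against 0 for ENSG00000175175.4. In the limma fit fixed beforehand, without the replicate number as a term, none of the 4 passed: the log2 differences of eCLIP minus input were 2.62 (SE 0.83), 2.65 (SE 0.93), -1.96 (SE 0.89) and -1.52 (SE 0.97), each with an adjusted p of 0.995.

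The last comparison, added after the data were seen, set out where along a gene the peaks fell. In 6536 genes with at least 20 peaks and a span of at least 5 kb, a smaller share of eCLIP than of input peaks lay at the 3′ end. The last of 10 equal parts of the span held 9.65% of the peaks of eCLIP replicate 1 and 8.77% of eCLIP replicate 2, against 13.8% of input 1 and 15.2% of input 2. The 95% intervals of the eCLIP libraries reached 9.73% and 9.06%, and those of the inputs began at 13.5% and 14.4%. The second part held 12.7% and 13.3% in eCLIP against 10.4% and 9.78% in the inputs, while the first part (15.9% and 15.6% against 13.7% and 16.9%) did not separate the groups. The reproducible eCLIP-only peaks lay in the last part in 9.60% of cases. Both eCLIP libraries lay below both inputs there, which an exact permutation test of 2 libraries against 2 cannot carry below a two-sided p of 0.33. Spans ran from the first to the last peak, so each gene has a peak at both ends by construction. Among the 11204 best-ranked peaks of each list the groups were not separated, with eCLIP replicate 1 at 16.2% and input 1 at 15.2%.

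**Figure D4:**
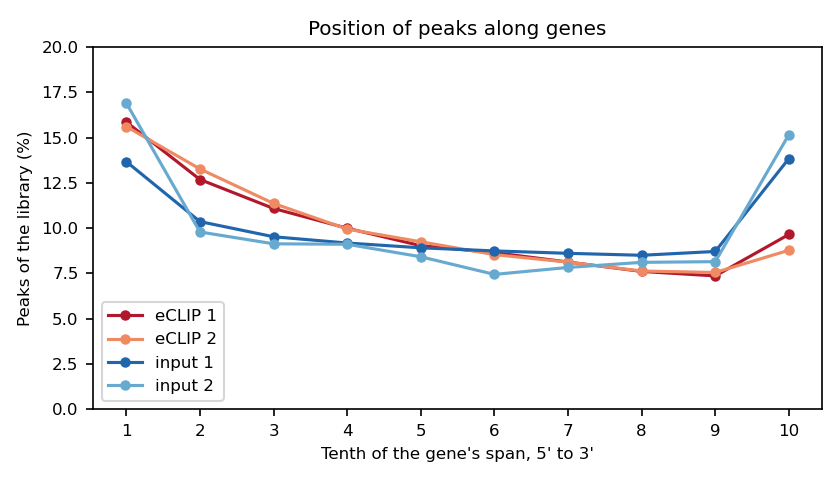
Share of a library's peaks (y axis, %) in each of 10 equal parts of the gene span, from the 5′ to the 3′ end, 1 line per library. In the last part the eCLIP libraries are at 9.65% and 8.77% and the inputs at 13.8% and 15.2%.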

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

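Chosen after the data were seen were the 50% overlap for peak strength, merging of touching peaks, reads per gene, the share of reads for the printed genes, placement within 10 kb, single counting of repeated intervals and the counts without an input. Over the results that answer a comparison, 39 of 53 alternatives kept the direction and the side of the threshold, or a count within 1.5 times. At a p-value limit of 0.001 the lists fell to 111520 and 9166 peaks for eCLIP and to 7927 and 3216 for the inputs, and the reproducible eCLIP-only peaks to 2486, since fewer peaks entered. In lists of equal length these were 1357. Otherwise they lay between 10589, with peaks within 50 bases merged, and 13523, with only peaks in both inputs removed. Without an input they lay between 12777 and 12813, and without an eCLIP library the set is not defined. The overlap of eCLIP replicate 2 with eCLIP replicate 1 stayed between 3.32 and 4.58 times the placements (permutation p = 0.0099 in each). Placement within 10 kb moved the ratios of pairs with an input more: from 5.02 to 9.30 for eCLIP replicate 2 in input 2, from 2.18 to 3.63 for it in input 1, and from 3.60 to 15.0 for input 2 in input 1. With a 50% overlap the differences in peak strength were 2.81 and 0.408. Leaving out single libraries gave between 0 and 695 higher genes, the highest without eCLIP replicate 2, and between 0 and 5 lower genes, the highest without input 1, with the lone library of a group assumed to vary like the other group. Voom called 8 genes lower, and Fisher's exact test in both numbered comparisons gave 2 higher and 3 lower. By share of reads in peaks, the log2 ratio of eCLIP over input for number 1 changed sign for ENSG00000251562.3, from -1.52 to 0.93. For ENSG00000167978.12 it moved from -1.99 to 0.044, which sets no direction, since touching intervals of input 1 may repeat reads. The cause was not tested. The replicate block called 3 genes higher and 1 lower, and ENSG00000173065.9 and ENSG00000175175.4 were among the higher ones. The labels give no shared origin to equal numbers, and across genes the deviations of same-numbered libraries from their group means correlated at r = 0.397. The cause of these changes in gene counts was not tested. For the 10 named regions, 90 of 110 counts stayed within 1.5 times, and the 20 others were those of the 0.001 limit and the equal lists. The planned tests of gene lists, list shares, region classes, splice-site distance and sequence were not run. Peaks of 3 reads were the smallest listed, which limits every overlap.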

Other observations

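Of the tests given here, the merging of touching peaks and the count of peaks shared by the eCLIP libraries in lists of equal length were chosen after the result was seen, and each weighed pattern was itself noticed in these data. Input 1 listed more peaks on the minus strand than the other libraries, 58.4% (58.0 to 58.8) of its distinct intervals against 48.0% and 48.9% in eCLIP and 48.8% in input 2. On that strand 39.6% of its intervals touched the next one, against 7.96% on its plus strand and at most 2.87% on either strand of the other libraries. With touching peaks merged, its minus-strand share was 47.9% (47.5 to 48.4), against 47.8%, 48.5% and 48.6%. Its median interval was 21 bases wide on the minus strand and 35 on the plus strand.

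Peaks in genes whose span exceeded 100 kb made up 50.1% and 46.0% of the lists of eCLIP replicate 1 and input 1, but 32.9% and 29.4% of those of eCLIP replicate 2 and input 2. The reproducible eCLIP-only peaks lay in such genes in 29.1% of cases. In the lists of equal length the shares were 20.7% and 29.1% for eCLIP and 44.3% and 29.4% for the inputs.

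Chromosome shares divided the libraries by replicate number more often than by group. Of 24 chromosomes, both libraries numbered 2 lay above both numbered 1 on 8 and below on 13, while both eCLIP libraries lay above both inputs on 2 and below on 1. Chromosome 19 held 10.4% and 9.26% of the peaks in eCLIP replicate 2 and input 2, but 5.75% and 5.20% in eCLIP replicate 1 and input 1, a gap of 3.52 percentage points between the nearest of these. The gap was -3.12 points in lists of equal length, where eCLIP replicate 1 was at 12.4% and input 1 at 4.64%, and -0.559 points with each gene counted once. List length or a few genes with many peaks may therefore account for part of the split of chromosome 19. In equal lists input 2, at 9.26%, still lay above input 1. The equal list is the whole of input 2 but only the best-ranked part of input 1. The cut therefore cannot tell whether list length accounts for the difference between the inputs. With each gene counted once, number 2 still lay above number 1 within eCLIP (8.33% against 7.57%) and within the inputs (7.01% against 6.44%). A batch that the labels do not record stays open, and no biological explanation was tested.

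A hypothesis is that the peaks shared by the eCLIP libraries alone are sites bound by ZFR, and 2 technical explanations were set against it. In lists of equal length the lower of the 2 counts (1237 peaks, on eCLIP replicate 2) was 1.49 times that of the next highest pair, eCLIP replicate 2 with input 2 (832 peaks), just under the 1.5 times set for excluding list length. Relative to placements within genes, equal lists of the eCLIP libraries overlapped 4.12 and 4.19 times as often as placed peaks, below the 5.67 times of eCLIP replicate 2 in input 2. List length and coincidence of peaks in strongly covered genes therefore both stay open for part of the set, beside binding of ZFR.

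A hypothesis from the position of peaks along genes is that ZFR bound RNA holding sequence away from the 3′ end, such as unspliced transcripts, more than the input did; introns were not analysed here. In the last of 10 parts of the span the lower input exceeded the higher eCLIP library by 4.19 percentage points over all peaks. The tests argue against different genes in different lists as the cause, since the 2852 of the 6536 genes that had peaks in all 4 libraries, weighted equally, gave 4.28 points. Spans set by eCLIP replicate 1 stay open: spans from the other 3 libraries gave 6.76 points, but these have the peaks of those libraries at their ends by construction. List length also may be the cause, since equal lists gave -1.04 points, with eCLIP replicate 1 at 16.2%, eCLIP replicate 2 at 8.85% and the inputs at 15.2% each.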
